A study of Mus musculus with 6 samples.

How the data were processed

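Gene expression was measured by RNA sequencing of polyadenylated transcripts (TruSeq Stranded mRNA kit, per the labels' protocols) in gastrocnemius muscle of 6 mice, 3 tamoxifen-treated and 3 vehicle-treated. The mice were fed a diet holding 0.81% calcium and vitamin D3 at 3.4 IU/g. Groups came from the phenotype recorded for each sample, vitamin D receptor knockout or vehicle control. Replicates were numbered 1 to 3 within each group only as names, so the groups were not paired.

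The deposited table gives a read count per gene for each library. Per the submitters' processing notes, bcl2fastq, STAR 2.6.1c and featureCounts from Subread 1.5.1 were used with the mm10 genome. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes, and close paralogs, are uncertain. The same deposited table gives an FPKM value per gene and library. These FPKM values equalled the count divided by the listed gene length plus 1 base and by the column total, to within rounding, so the deposited FPKM carry no normalization beyond library total. The table lists 43346 genes, of which 19501 were at 0 in all libraries. All 37 genes of the mitochondrial chromosome were listed at 0 in every library, so that mitochondrially encoded transcripts could not be examined. All value columns belonged to the 6 libraries.

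Library totals ran from 30486874 to 39909535 reads. A count of 3, taken as the floor, corresponded to 0.0752 to 0.0984 CPM.

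Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15583, and scaled with TMM factors that ran from 0.912 to 1.13. A quasi-likelihood model with robust estimation compared knockout with vehicle, two-sided, and p values were adjusted by Benjamini-Hochberg over all genes kept, with a threshold of 0.05. The common biological coefficient of variation was 0.270. Fold changes are log2 of knockout over vehicle, with standard errors derived from the F statistic, and CPM values use TMM-scaled library sizes.

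Before the data were examined, 40 gene lists for pathways, fibre types and cell types were fixed, along with the tests, the rule for named genes and most alternatives. Of these lists, 37 had at least 3 members that passed the filter. The mitochondrially encoded list was at 0, and the lymphocyte and the bone and cartilage lists had 2 members each that passed, so none of these was tested. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists by Benjamini-Hochberg. Adjusted p values quoted for a list are from camera unless another test is named. Members were also adjusted over their list alone, using the edgeR p values. Principal components were computed on the 500 most variable genes.

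The rule for named genes was as follows. Vdr and Esr1 were always named. From genes past the threshold with a mean CPM of at least 1 and no overlap between groups, the 12 largest changes in each direction would be named. If fewer than 10 passed, the 10 of smallest p in each direction that met the other conditions were named instead, stated as not past the threshold. Unnamed gene models and pseudogenes were left out. For each list, up to 4 passing members or up to 3 members of smallest p were named, except 1 gene that is not reported here. Other list members named in the text (Fos, Egr1, Myh7, Tnni1, Adipoq, Xaf1, Gbp2, Dbp, Tef, the genes at the ends of the first component and the members added under the other observations) were chosen after their values were seen.

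The procedure was tested on simulated counts drawn with the real means, library sizes and dispersions for the comparison of knockout with vehicle. Of 100 genes changed 2-fold, edgeR recovered 35%, and of 100 changed 4-fold it recovered 79%, among 15274 genes, with 8 false calls. DESeq2 1.42.0 recovered 47% and 85% among 15583 genes, with 31 false calls. With no gene changed, edgeR made 1 call and DESeq2 6. Each gene was drawn independently, without the variation that many genes share across the real libraries. These recovery and false call numbers may therefore not hold for the real data. In 1 split of the real libraries other than by treatment, the highest such count, DESeq2 called 234 genes. Camera at its preset correlation, on simulated counts without correlation, called the 1 shifted list and 0 of the others.

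Alternatives included DESeq2 size factors and upper-quartile factors in edgeR, the DESeq2 Wald test, limma-voom with and without sample quality weights, and limma on log2(FPKM + 0.1) and log2(FPKM + 1). Others were no low-count filter, a stricter filter of 1 CPM in 3 libraries, estimation without robustness, an adjusted threshold of 0.1, a minimum fold change of 1.2 and leaving out each library in turn. Matched random lists were drawn 10000 times from the 100 nearest genes to each member in expression, gene length and GC content, the latter from GENCODE M21 transcripts.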

Results

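RNA was sequenced from the gastrocnemius muscle of 6-month-old male mice in which exon 3 of the vitamin D receptor gene Vdr was flanked by loxP sites and which carried a tamoxifen-inducible Cre recombinase driven by the human skeletal actin promoter. The knockout group comprised 3 mice given tamoxifen and the control group 3 mice of the same genotype given vehicle, 1 library per mouse. Each dose was 100 mg/kg in 75 microliters of 10% ethanol in corn oil, injected for 5 days. Tests of glucose handling and strength followed 10 days after the last injection, and muscle was collected once they were complete. The libraries held between 30486874 and 39909535 counted reads. Knockout replicate 2 had the fewest reads and the smallest share in its 10 most abundant genes, 15.1%, against 20.8% to 25.2% in the other 5 libraries. No pair of libraries agreed within sampling noise, so none looked like a copy of another. Each counted as a separate replicate because it came from a separate mouse.

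Vdr, the nuclear receptor that the loxP sites target, was scarcely expressed in this muscle and was not detectably lower in the knockout libraries. The 3 knockout libraries held 52, 27 and 40 Vdr reads and the 3 vehicle libraries 46, 48 and 61. Counts scaled to library size (CPM) were 1.12 ± 0.368 (SD, n = 3) in the knockout group and 1.44 ± 0.139 (SD, n = 3) in the vehicle group. The log2 fold change was -0.37 (SE 0.37, 95% interval -1.19 to 0.46; edgeR adjusted p = 0.848). Vdr (ENSMUSG00000022479) lies on chromosome 15 from 97854425 to 97910630 in mm10. In its reference transcript the floxed exon 3 spans 97884794 to 97884941, of which 146 bases are coding, and its 148 bases make up 2.62% of the gene length listed with the counts. Loss of that exon's own reads would therefore hardly register in a gene-level count. Any effect of the deletion on the rest of the transcript was not measured separately, and these counts are only a partial check of the labels. Deletion, Cre activity and tamoxifen came together in these libraries, since the tamoxifen-treated mice without Cre that the protocol describes were not analysed here.

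The transgene also carries a mutated estrogen receptor sequence, so reads assigned to Esr1 can come from the transgene as well as from the mouse's own receptor. Esr1 ranked 104 among all tested genes by mean CPM, above the other receptors examined for comparison, among them Nr4a1 at rank 140 and Nr3c1 at rank 817. Its CPM was 918 ± 662 (SD, n = 3) in knockout and 1017 ± 602 (SD, n = 3) in vehicle libraries, a log2 fold change of -0.15 (SE 0.55) whose sign turned when knockout replicate 2, knockout replicate 3 or vehicle replicate 2 was left out. Knockout replicate 1 and vehicle replicate 2 stood apart at 1682 and 1708 CPM, while the other 4 libraries lay between 496 and 729. The receptors in this comparison were chosen after their values were seen.

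The comparison of knockout with vehicle asks which transcripts differ in gastrocnemius after Vdr deletion is induced in adult muscle. The genes that separated the groups most clearly included, on the higher side, Iigp1, an interferon-induced GTPase, and Pik3r1, a regulatory subunit of the lipid kinase that acts downstream of the insulin receptor. On the lower side they included Atf3, a stress-induced transcription factor, and Nmrk2, a muscle enzyme of nicotinamide adenine dinucleotide synthesis. Iigp1 averaged 19.6 ± 3.84 CPM in knockout and 5.70 ± 0.158 in vehicle libraries (SD, n = 3 each), a 3.44-fold difference. Atf3 averaged 85.8 ± 10.1 and 248 ± 27.5 CPM, respectively. None of these differences passed the threshold: of 15583 genes tested with edgeR, 0 had an adjusted p below 0.05, 7 were below 0.1 and the smallest adjusted p was 0.058. At an unadjusted p below 0.05 there were 1159 genes, 626 higher and 533 lower in knockout, where 779 would be expected by chance. That count varied when a library was left out: it was 594 without vehicle replicate 3, 738 without knockout replicate 2 and 748 without vehicle replicate 2. Without knockout replicate 3 it was 961, without vehicle replicate 1 it was 1502 and without knockout replicate 1 it was 1940. These fits hold fewer libraries and tested 15949 to 16126 genes, so a lower count does not show that a single library carried it. With all 6 libraries the count was 286 with the slow-twitch list mean as a covariate and 469 with the macrophage list mean, both fits chosen after seeing the data. The groups did not overlap in 1918 genes, 12.3% of those tested, where chance gives 10%.

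The count of called genes varied with the tool. DESeq2 called 109 genes, 52 higher and 57 lower, edgeR without a low-count filter called 29, and limma-voom with sample quality weights and edgeR with DESeq2 size factors called 4 each. Leaving out knockout replicate 1 gave 24 genes and leaving out knockout replicate 2 gave 6, whereas leaving out any of the other 4 libraries gave 0.

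Because fewer than 10 genes passed, the genes named next are the 10 of smallest p in each direction whose libraries did not overlap between groups, and none passed the threshold in edgeR. All 20 were called by DESeq2, but they were picked for small p in these same libraries, so this is no independent support. On the higher side the log2 fold change was 1.78 (SE 0.20) for Iigp1, 3.46 (SE 0.42) for Flrt1, a leucine-rich repeat membrane protein, 1.07 (SE 0.14) for Pik3r1 and 1.61 (SE 0.23) for the synaptotagmin Syt12. Their adjusted p values were 0.058, 0.058, 0.077 and 0.0997. The kinase gene Sbk3 followed at 3.85 (SE 0.59), with knockout replicate 2 far above the others, then the guanylate-binding protein Gbp7 at 1.26, the xenobiotic-metabolizing Cyp1a1 at 2.34, Lrrn1 at 1.505, the protease Adamts8 at 2.94 and the cytosolic isocitrate dehydrogenase Idh1 at 0.91. On the lower side the values were -1.53 (SE 0.18) for Atf3, -2.38 (SE 0.29) for the axonemal protein Tekt1 and -1.86 (SE 0.25) for Nmrk2, with adjusted p values of 0.058, 0.058 and 0.077. Dkk3, a secreted member of the dickkopf family, was at -2.46, the spindle protein Tpx2 at -1.76, the transcriptional repressor Bcl6 at -1.24, the nuclear receptor coactivator Pnrc1 at -1.25 and the chemokine Cxcl10 at -2.93. Chrne, the adult subunit of the muscle acetylcholine receptor, was at -1.23 and Ppp1r15a, which directs the dephosphorylation of a translation initiation factor under stress, was at -1.07.

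**Figure D1:**
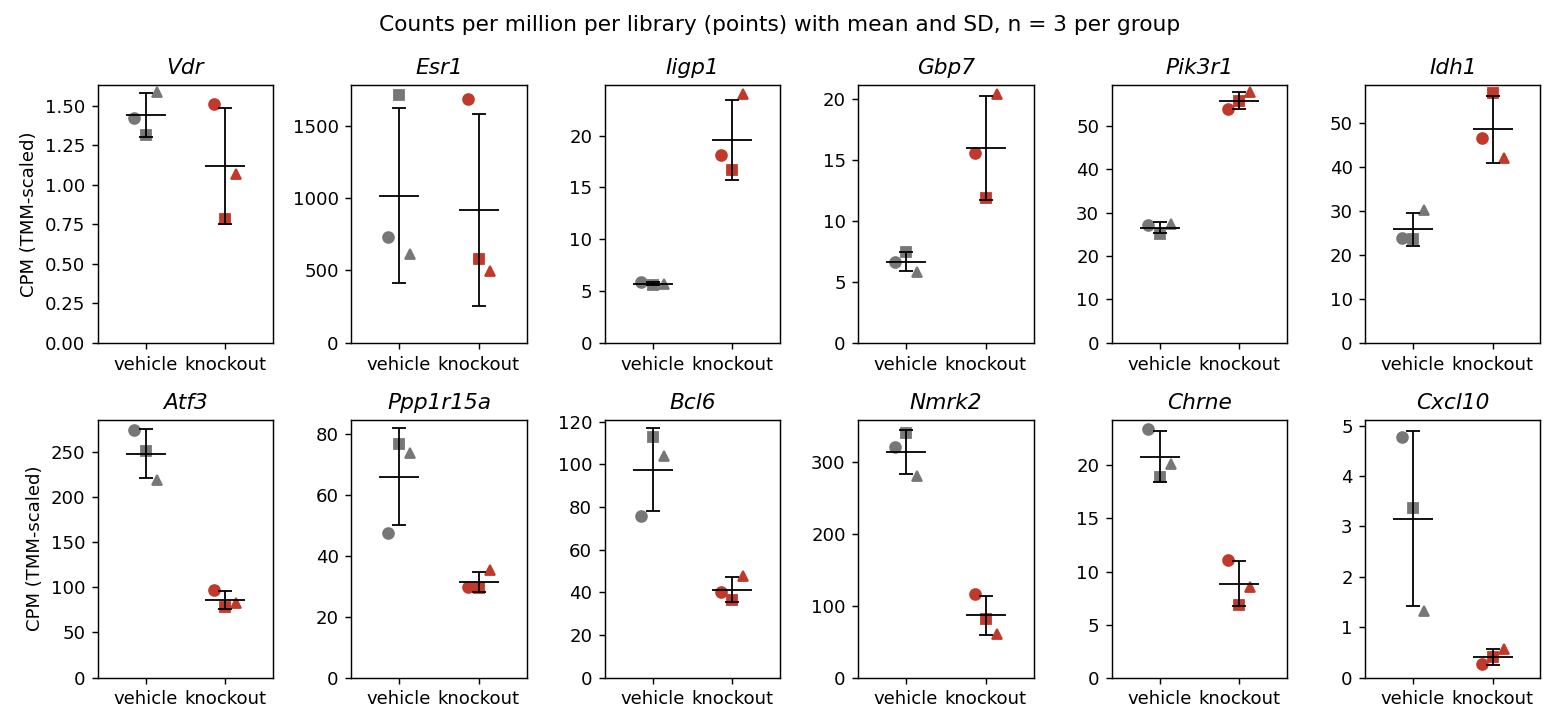
Each panel plots CPM (TMM-scaled, linear axis from 0) of 1 gene in vehicle (gray) and knockout (red) libraries, with circles, squares and triangles for replicates 1, 2 and 3 and a bar with whiskers for the mean and SD (n = 3). Iigp1 lies between 16.7 and 24.0 in the knockout and between 5.59 and 5.88 in the vehicle libraries, whereas Vdr and Esr1 overlap between groups.

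Interferon-induced genes had the smallest camera p of the 37 lists tested. Of 29 measured members, 28 had a higher estimate in knockout, with a median log2 fold change of 1.00. With camera at its preset correlation the list was called higher (adjusted p = 8.74e-12), and with an estimated correlation it was not (adjusted p = 0.572). Adjusted over the list alone, 5 members passed: Gbp3 at 1.95 (SE 0.39), the immunoproteasome subunit Psmb8 at 1.32 (SE 0.32), Ifit3 at 1.15 (SE 0.31), Xaf1 at 1.10 (SE 0.31) and Gbp2 at 1.21 (SE 0.35). Over all genes 0 passed. Each of the 5 kept that status in at most 3 of the 6 fits that left out a library, and reads of the Gbp paralogs can be split between copies. Macrophage and myeloid markers were also highest in knockout replicates 2 and 3: their list mean, relative to the mean of the 6 libraries, was 1.05 and 0.82 in knockout replicates 2 and 3 and -0.58 in knockout replicate 1, against -0.36, 0.0371 and -0.97 in vehicle replicates 1, 2 and 3. The interferon list mean in those libraries was 0.84, 0.68 and -0.23, and it was -0.31, -0.35 and -0.62 in the vehicle libraries, so knockout replicate 1 lay below vehicle replicates 1 and 2 in macrophage markers and above them in interferon genes. Cxcl10, itself an interferon-induced chemokine, went the other way at 0.409 ± 0.150 CPM in knockout and 3.16 ± 1.73 in vehicle libraries (SD, n = 3 each). Cxcl10 passed when adjusted over the inflammation and acute phase list alone (adjusted p = 0.00579). That list had 18 of 20 members with a lower estimate and was called lower by camera (adjusted p = 0.0143; 0.572 with an estimated correlation), a call lost without vehicle replicate 2 (adjusted p = 0.558).

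Immediate early genes, which are induced within minutes of a stimulus, mostly had lower estimates in knockout. Of 25 members, 22 had a lower estimate, and the median log2 fold change was -0.73. The list mean separated all 3 knockout from all 3 vehicle libraries, as in 5 of the 37 lists tested, where chance gives 10%. Camera called the list lower (adjusted p = 1.21e-10), and the adjusted p was 0.572 with an estimated correlation. Adjusted over the list alone, Atf3 and Myc passed, Myc at -1.20 (SE 0.29), and over all genes 0 passed. Atf3 kept that status in all 6 fits that left out a library and Myc in 3. Junb was at -0.71 (SE 0.22), Fos at -1.12 (SE 0.37) and Egr1 at -1.01 (SE 0.50). In the p53 and DNA damage list, 18 of 22 members were lower in estimate (camera adjusted p = 6.49e-04; 0.572 with an estimated correlation), and 2 passed over the list alone, Gadd45b at -1.04 and the stress-induced Sesn1 at 0.63, which kept that status in 2 and 1 of the 6 fits that left out a library. The endoplasmic reticulum stress list was not called (adjusted p = 0.789), although Atf3 and Ppp1r15a passed when adjusted over that list alone. Neither the heat shock list (adjusted p = 0.357) nor the FoxO and atrophy list (adjusted p = 0.128) was called. In the latter the ubiquitin ligase Fbxo32 was at -0.91 (SE 0.30). Of 19 circadian clock genes, 15 had a lower estimate, among them Cry2 at -0.78 (SE 0.25), and Per3 had a higher one at 0.59 (SE 0.21). The clock list was called lower (adjusted p = 0.00244; 0.572 with an estimated correlation), a call lost without knockout replicate 2 (adjusted p = 0.122).

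Slow-twitch fibre genes varied more between libraries than any other list. All 15 had a higher estimate in knockout, with a median log2 fold change of 1.82, and 0 passed when adjusted over the list alone. The slow myosin heavy chain Myh7 was at 1.82 (SE 1.04), the slow troponin Tnni1 at 1.90 (SE 1.09), the calsequestrin Casq2 at 1.79 (SE 0.66) and Myoz2 at 1.79 (SE 0.70). Camera called the list higher (adjusted p = 5.03e-08), with an adjusted p of 0.572 with an estimated correlation, which was 0.946 for this list. The median difference in log2 CPM was 2.11, with 1.40 without knockout replicate 2 and 3.05 without vehicle replicate 1. The list mean was 2.27 in knockout replicate 2, 0.58 and 0.08 in the other knockout libraries, and 0.72, -1.71 and -1.93 in vehicle replicates 1, 2 and 3. Fast-twitch genes had 15 of 17 estimates lower (adjusted p = 7.32e-04; 0.607 with an estimated correlation), and without knockout replicate 2 they were not called (adjusted p = 0.142). The fast kinase gene Mylk2 was at -0.84 (SE 0.28), while Myh2 and Myh1, which encode the intermediate fast myosins, were at 1.12 (SE 0.49) and 0.63 (SE 0.32). The myosin heavy chain genes are close paralogs whose reads can be misassigned.

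Genes of oxidative metabolism mostly had higher estimates in knockout. Fatty acid uptake and oxidation genes had 33 of 36 estimates higher (adjusted p = 4.76e-07; 0.572 with an estimated correlation), including Acads at 0.64 (SE 0.20), Lipe at 0.80 (SE 0.27) and the fatty acid transporter Cd36 at 0.94 (SE 0.34). Their median difference in log2 CPM, 0.43, was 0.25 without knockout replicate 2 and 0.27 without vehicle replicate 2. The fatty acid list mean was 0.0426, 0.55 and 0.0600 in knockout replicates 1, 2 and 3 and 0.13, -0.45 and -0.34 in the vehicle replicates, beside slow-twitch means of 0.0819, 2.27 and 0.58 and of 0.72, -1.71 and -1.93. Lipe is also a member of the adipocyte list, in which 15 of 15 estimates were higher in knockout. Oxidative phosphorylation genes had 72 of 78 higher (adjusted p = 2.85e-04; 0.695 with an estimated correlation), with a median of 0.22, and were not called without knockout replicate 2 or without vehicle replicate 2 (adjusted p = 0.848 and 0.775). Their median difference in log2 CPM, 0.21, was 0.0169 and 0.0343 in those fits and 0.35 without knockout replicate 3. The tricarboxylic acid cycle list had 22 of 26 higher (adjusted p = 0.0116; 0.646 with an estimated correlation), among them Pcx at 0.83 (SE 0.31) and Mdh1 at 0.61 (SE 0.30). It was not called without knockout replicate 1 or vehicle replicate 2 (adjusted p = 0.166 and 0.484). Glycolysis genes had 13 of 18 lower (adjusted p = 0.0429; 0.646 with an estimated correlation), including Aldoa at -0.48 (SE 0.35), and lost the call in 5 of the 6 fits that left out a library. The glycogen metabolism list was not called (adjusted p = 0.128), nor was the cholesterol biosynthesis list (adjusted p = 0.306).

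In the insulin signalling and glucose uptake list, which was not called as a group (adjusted p = 0.128), Pik3r1 passed when adjusted over the list alone (adjusted p = 0.00116) and did so in all 6 fits that left out a library. Pik3r1 averaged 55.8 ± 1.98 CPM in knockout and 26.6 ± 1.24 in vehicle libraries (SD, n = 3 each). Grb14, an adaptor that binds the insulin receptor, was at 0.98 (SE 0.30) and Tbc1d4, which governs glucose transporter traffic, at 0.65 (SE 0.20), and neither passed. The vitamin D list was not called (adjusted p = 0.357), with the retinoid receptors Rxrg at -0.70 (SE 0.25) and Rxra at -0.24 (SE 0.22) and the vitamin D hydroxylase Cyp27a1 at -0.53 (SE 0.26). The estrogen response list was not called (adjusted p = 0.376), with 8 of 13 estimates higher and 5 lower. Its members of smallest p were Amotl2 at 0.46 (SE 0.17), Greb1 at 1.11 (SE 0.42) and Slc7a5 at -0.92 (SE 0.37). Over the list alone 0 passed. Greb1 was weakly expressed, at 1.17 ± 0.349 CPM in knockout and 0.543 ± 0.0678 in vehicle libraries (SD, n = 3 each). The list test does not exclude a response to tamoxifen.

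Among neuromuscular and myogenic genes, Chrne and the myogenic factors Myog and Myf6 were lower in knockout and passed when adjusted over their lists alone. Chrne averaged 8.86 ± 2.12 CPM in knockout and 20.8 ± 2.37 in vehicle libraries, Myog 12.7 ± 4.17 and 29.7 ± 7.87, and Myf6 115 ± 24.9 and 236 ± 26.0 (SD, n = 3 each). Chrne passed in all 6 fits that left out a library, and Myog and Myf6 in 5. The neuromuscular junction list (adjusted p = 0.486) and the myogenic list (adjusted p = 0.379) were not called, and Dok7 was higher in estimate at 0.63 (SE 0.20). Excitation-contraction coupling genes had 22 of 34 lower (adjusted p = 0.0442; 0.646 with an estimated correlation), with Cacng1 at -0.96 (SE 0.27), and lost the call in 5 of the 6 fits that left out a library. The proteasome list had 30 of 31 lower, with a median of -0.20 (adjusted p = 5.99e-05; 0.601 with an estimated correlation), or -0.12 without knockout replicate 3 and -0.10 without vehicle replicate 3, and Psmd8 at -0.80 (SE 0.18) passed over the list alone but in 0 of the 6 fits that left out a library. Polyamine genes had 8 of 13 lower (adjusted p = 0.0116; 0.572 with an estimated correlation), among them Sms at -0.89 (SE 0.23) and Amd1 at -1.20 (SE 0.50), whose copy Amd2 may share its reads. The polyamine list was not called without knockout replicate 3 or vehicle replicate 3 (adjusted p = 0.0529 and 0.0517). Cell cycle genes were not called (adjusted p = 0.439; median 0.00, mean -0.08), although Tpx2 passed over the list alone, and ribosomal protein genes were not called (adjusted p = 0.747).

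Markers of other cell types differed between libraries. Adipocyte markers had 15 of 15 estimates higher in knockout (camera adjusted p = 2.41e-06; 0.572 with an estimated correlation), with Adipoq at 1.21 (SE 0.47). Their median difference in log2 CPM, 0.93, was 0.62 without vehicle replicate 3. Macrophage and myeloid markers had 16 of 17 higher (adjusted p = 3.17e-05; 0.572 with an estimated correlation), including C1qa at 1.23 (SE 0.41) and Csf1r at 1.29 (SE 0.45). The corresponding difference, 0.82, was 0.51 without knockout replicate 2 and 1.43 without knockout replicate 1. Extracellular matrix genes had 29 of 31 higher (adjusted p = 1.40e-04; 0.646 with an estimated correlation), among them Postn at 1.32 (SE 0.52) and Lum at 0.95 (SE 0.34). The fibroblast list had 14 of 15 higher (adjusted p = 0.00252; 0.646 with an estimated correlation). Without vehicle replicate 3 the matrix list was not called (adjusted p = 0.0548), and without knockout replicate 2 the fibroblast list was not called (adjusted p = 0.346). Schwann cell markers had 12 of 13 lower (adjusted p = 4.76e-04; 0.572 with an estimated correlation), with Mbp at -0.63 (SE 0.31), and their list mean was highest in vehicle replicate 2 at 0.88. Their median difference in log2 CPM, -0.59, was -0.33 without that library. In the smooth muscle list, which was not called (adjusted p = 0.154), Cnn1 at -1.60 (SE 0.41), Acta2 at -0.76 (SE 0.20) and Tagln at -0.61 (SE 0.18) passed when adjusted over the list alone. Cnn1 and Acta2 did so in 4 of the 6 fits that left out a library and Tagln in 2. In the endothelial list, which was not called (adjusted p = 0.923), Cldn5 at -0.91 (SE 0.20) passed in the same way, and in 3 of the 6 fits. Satellite cell, tendon, erythroid and epithelial lists were not called (adjusted p = 0.510, 0.746, 0.789 and 0.481). In all, camera called 19 of 37 lists at its preset correlation, 9 higher and 10 lower. With an estimated correlation it called 0, and the rotation test fry called 0 (smallest adjusted p = 0.282). Adjusted over each list alone, 23 of 862 memberships passed. The signs of median, mean and test differed for 5 lists, none of them called: cell cycle, neuromuscular junction, ribosomal proteins, endoplasmic reticulum stress and endothelial markers.

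**Figure D2:**
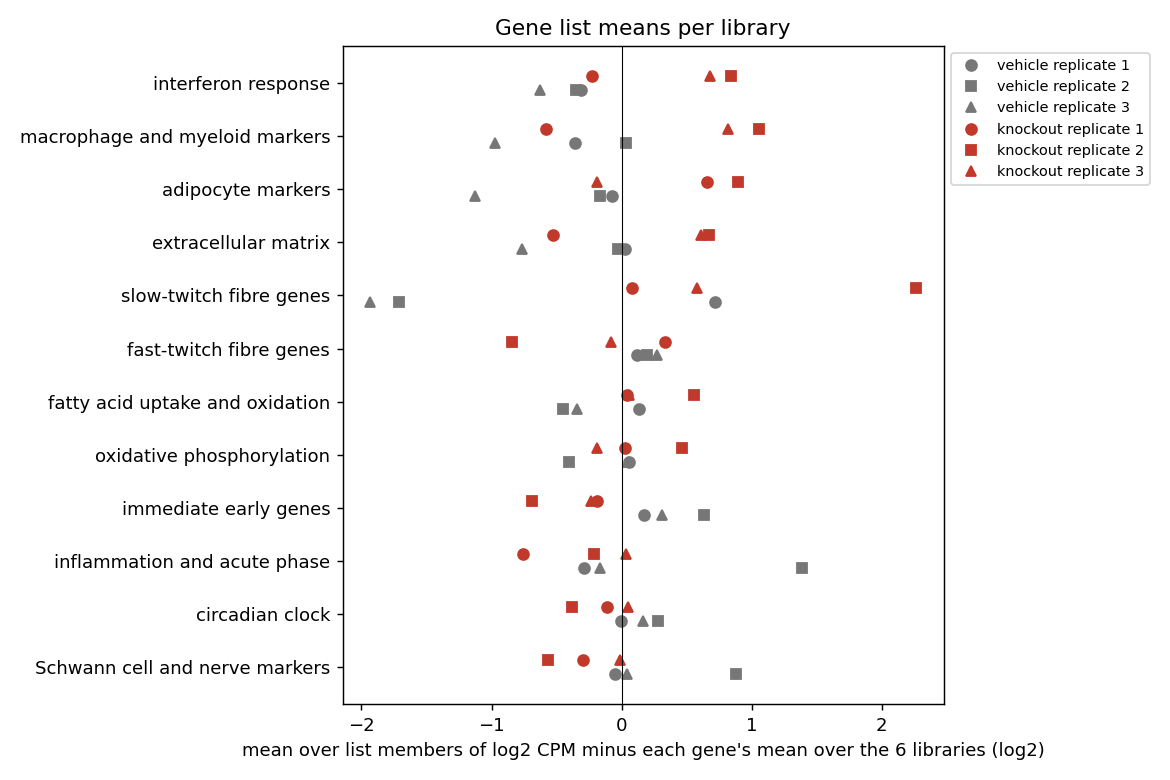
The horizontal axis is the mean over a list's members of log2 CPM minus each gene's mean over the 6 libraries (log2 units), for 12 lists on the vertical axis, with 1 point per library colored gray for vehicle and red for knockout. The slow-twitch list runs from -1.93 in vehicle replicate 3 to 2.27 in knockout replicate 2. The interferon and immediate early lists are among the 5 of 37 tested lists whose means separate the groups, where chance gives 10%.

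The largest axis of variation between libraries did not separate the groups. The first principal component of the 500 most variable genes held 51.5% of their variance and had Myl3, Tnni1 and Myh7 of the slow-twitch list, together with Sbk3 and Myh6, at its positive end. The loading of largest absolute size was that of Rmi2, at the negative end with Ppm1n and Hsd17b14. Its score was 40.1 in knockout replicate 2 and 7.07 and -3.72 in the other knockout libraries, against -2.26, -18.0 and -23.2 in the vehicle libraries. The group means differed by 29.0 (exact two-sided permutation p = 0.2, where 0.1 is the smallest value that 3 against 3 libraries allow).

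**Figure D3:**
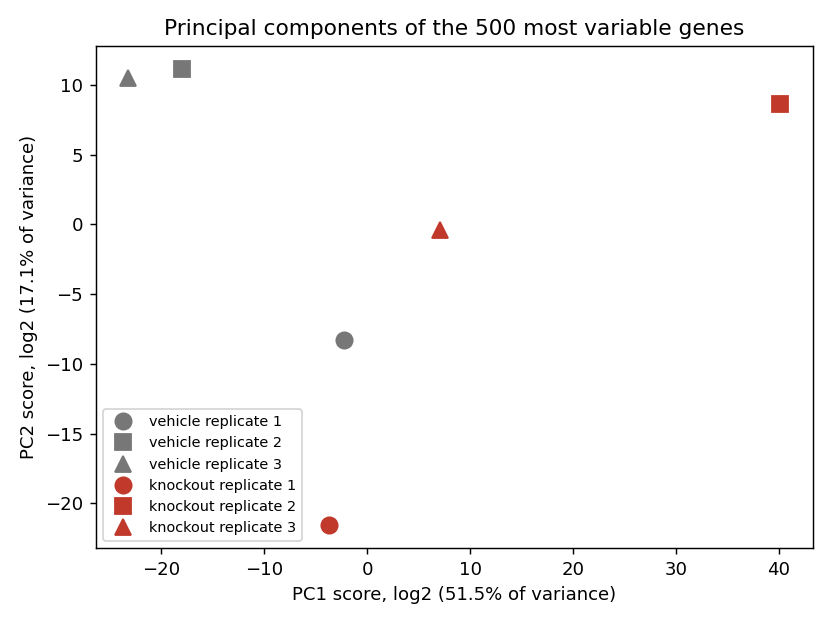
Scores on the first (horizontal, 51.5% of variance) and second (vertical, 17.1%) principal components of log2 CPM, with 1 point per library, gray for vehicle and red for knockout. Knockout replicate 2 lies at 40.1 on the horizontal axis, while knockout replicate 1 at -3.72 and vehicle replicate 1 at -2.26 lie side by side.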

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

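The covariate fits and all alternatives for members adjusted over their list alone were chosen after seeing the data. The count of called genes, 0 with edgeR, was 4 with DESeq2 size factors, 109 with DESeq2, 4 with limma-voom and quality weights, 29 without a low-count filter and 7 at a threshold of 0.1. Leaving out a library gave 0 to 24 (24 without knockout replicate 1, 6 without knockout replicate 2), and the cause was not tested. It was 0 with upper-quartile factors, limma-voom, limma on both FPKM scales, the stricter filter, estimation without robustness, the minimum fold change and both covariates. Vdr stayed below 0 (-0.64 to -0.06) and short of the threshold in every alternative. Camera's 19 lists became 0 with an estimated correlation and 0 with fry, neither of which uses the preset correlation of 0.01. The number was 15 to 20 when a library was left out. Correlation between members does not explain every lost call. The polyamine list had an estimate of -0.0175, below the preset, yet its unadjusted camera p rose from 0.00501 to 0.0411. A lost call therefore does not show by itself that correlation between members produced the call at the preset value. The simulations ran camera at its preset correlation only, so the power with an estimated correlation or with fry was not checked. The adjusted p of 0.572 is shared by lists with different unadjusted p, such as 0.0312 for immediate early genes and 0.229 for macrophage markers. Members passing over their list alone, 23 in the full data, ran from 8 without vehicle replicate 3 to 113 without knockout replicate 1, and 18 of the 23 were among those 113. Signs turned for a few weak estimates, none past the threshold over all genes. With the slow-twitch mean as a covariate the log2 values became 0.49 for Esr1, 0.00075 for Cyp27a1, 0.0805 for Ppp1r3c, 0.10 for Bpgm, -0.15 for Uqcrq, -0.0229 for Ndufa11, -0.25 for Hspb7, 0.0674 for Ptx3, -0.0397 for Rplp1, -0.0292 for Kdr and 0.43 for Alas2. Alas2 was also at 0.0411 with limma-voom, at 0.15 and 0.0655 on the FPKM scales with pseudocounts of 0.1 and 1, and ran from -1.12 to 1.10 when a library was left out. Over the same fits Esr1 ran from -0.93 to 0.45, both genes being highest without vehicle replicate 2, and Esr1 was at 0.0989 and 0.15 without knockout replicates 2 and 3. The ribosomal protein list ran from -0.14 without knockout replicate 2 to 0.13 without knockout replicate 3, with 0.11 without vehicle replicate 3, and was past the threshold in these 3 fits. The erythroid list ran from -0.50 to 0.95, passing without vehicle replicate 2. Leaving out mitochondrial genes moved nothing, since all are listed at 0. No paired analysis was possible because the labels give no shared replicate numbers. Depth limits Vdr, at 27 to 61 reads per library.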

Other observations

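Tests chosen only after the results were seen were the macrophage covariate, the chromosome count, the clock genes, the matched lists, the spread of the slow-twitch genes and the splits counted with DESeq2.

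Among adipocyte genes not yet described, Cfd was at 1.78 (SE 0.63), Retn at 1.40 (SE 0.51), Cidec at 1.39 (SE 0.55) and Lep at 1.37 (SE 0.59) on the log2 scale, all higher in estimate in knockout and none past the threshold. In the interferon list, Ifi44 was at 1.75 (SE 0.78), Mx2 at 1.62 (SE 0.65), Psmb9 at 1.46 (SE 0.46), Tap1 at 1.44 (SE 0.55) and Rtp4 at 1.35 (SE 0.52), while Usp18 was at -0.15 (SE 0.27). Among immediate early genes, Klf4 was at -0.96 (SE 0.34), Ier3 at -0.82 (SE 0.27), Dusp1 at -0.73 (SE 0.27) and Zfp36 at -0.59 (SE 0.23), while Ctgf was at 0.29 (SE 0.52). None of these passed over all genes.

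The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. With edgeR all 10 splits gave 0 genes, the highest of the others being 0. With DESeq2 the real split gave 109 genes and 2 splits, the real one included, gave as many, the highest other being 234. That split set knockout replicate 1 with vehicle replicates 2 and 3, the 3 libraries lowest in slow-twitch genes. It gave 1719 genes at an unadjusted edgeR p below 0.05, against 1159 for the real split. A grouping other than by treatment can thus give as many genes. The split was singled out after its count was seen, and what drives it was not tested. With camera the real split called 19 lists, the highest other called 18, and 1 split, the real one itself, gave as many.

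Interferon-induced genes were higher in estimate in knockout. The 28 list members with higher estimates lie on 13 chromosomes, with at most 5 on any 1, so they do not lie in 1 inherited region. An inherited region that acts on genes elsewhere would leave the same count, so the count cannot exclude it. With the macrophage list mean as a covariate, the median over the 29 list members went from 1.00 to 0.26, while 25 members stayed above 0, against 28 without it. Macrophage content may account for part of the list and cannot be told apart from an effect of treatment there, with only 6 libraries. In the same fit Iigp1 went from 1.78 to 1.74 (SE 0.24), Gbp7 from 1.26 to 1.21 (SE 0.28) and Gbp3 from 1.95 to 1.10 (SE 0.32), but these genes were picked for separating the groups and exclude nothing. Deletion of Vdr, Cre activity and tamoxifen remain open as biological explanations and were not separated.

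Immediate early genes were lower in estimate in knockout. Their median of -0.73 lay at percentile 0 of 10000 random lists matched on expression level, gene length and GC content, which argues against a bias in these properties. Time of day at collection could also lower such genes and cannot be told apart from treatment. The clock list had 15 of 19 estimates lower and was called lower by camera (adjusted p = 0.00244; 0.572 with an estimated correlation). That call was lost without knockout replicate 2. Over their list alone 0 clock genes passed (smallest adjusted p = 0.0915), although 6 had an unadjusted edgeR p below 0.05. Among those 6, Bhlhe41 was at -0.86 and Nr1d1 at -0.59, while only Per3, at 0.59, was higher. The interval of Nr1d2 ran from -0.42 to 0.42. The intervals of Dbp (-0.38 to 0.51) and Tef (-0.48 to 0.51) still allow shifts. The labels give no collection times, and handling at collection was not tested. An effect of treatment stays open.

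The slow-twitch list mean ranged more widely between libraries than that of any other of the 37 lists tested. The median of 1.82 lay at percentile 100 of 10000 matched lists, which argues against expression level, gene length or GC content. A single divergent library, knockout replicate 2, is argued against as the whole cause of the spread between libraries. The other 5 libraries still ranged over 2.65 log2 units, which is the range of the vehicle libraries. Without knockout replicate 2 the difference between group means was 1.31, against 1.95 with all libraries. The part of the muscle sampled may differ between mice, since the vehicle libraries alone ranged over 2.65 log2 units and Myh7 differed 18.2-fold among them. That range and the 1.95 between group means are unlike measures, so their sizes do not decide the question. Fast-twitch list means were 0.12, 0.20 and 0.27 in vehicle replicates 1, 2 and 3, opposite in order to the slow-twitch means but narrow in spread. In knockout replicates 1, 2 and 3 they were 0.34, -0.84 and -0.08. The part sampled cannot be told apart from an effect of treatment because no measure of the sampled region was analysed here.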
